A study of Mus musculus with 8 samples.

How the data were processed

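Cytosine methylation was measured by HELP-tagging in liver DNA of 8 C57BL/6J mice. Of these, 4 had received a high-fat diet with lingonberries and 4 the high-fat diet alone (HFD). HELP-tagging rests on HpaII, an enzyme that cuts CCGG only where the central CpG is unmethylated, and on MspI, which cuts the same sequence whether or not it is methylated. A short tag is sequenced from each cut end, so a site with many HpaII tags relative to its MspI tags is unmethylated. Per the labels' protocols, phenol-chloroform extracted DNA was digested with HpaII, and tags were made with adapter ligation, EcoP15I digestion, in vitro transcription, reverse transcription and PCR, with no molecular identifiers named. Tags are therefore not independent molecules, and statements on depth cover counting error only.

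Each deposited file holds 1 sample and lists, per HpaII site, a chromosome, a position and 2 measurements. The first, per the file headers, is an m-score, a score that ran from 0 to 100. The second, per the file headers, is named conf and was treated as a signal that is never negative. Both meanings were worked out from the values. The m-score behaved as the angle of the vector formed by MspI and HpaII tags, with 0 where a site had no HpaII tag (the methylated end of the scale) and 100 where it had no MspI tag (the unmethylated end). The conf signal behaved as the length of that vector. The submitters' processing notes name the mouse build mm9 and CASAVA, with no version or role. The tag aligner, the origin of the MspI reference and the filters on tags are not given in the sources used here.

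HpaII tags were recovered as the sine component of each vector and MspI tags as the cosine component. The recovered HpaII values were whole numbers, within a tolerance of 0.02, at 96.6% to 97.2% of the sites above 0 in each sample. Fractional values were read as tags shared between several sites, which affected 148029 sites (11.3%). The MspI component had a single ratio between any pair of files, so 1 MspI reference of 29676321 tags had been scaled to the HpaII total of each file. It cancels from comparisons of tags between groups at a site, and it sets the weight of a single HpaII tag on the m-score. As the deposited values are scores and not counts, the design fixed before the data were examined called for limma on the m-score in place of a count model.

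Depth was the sum of recovered HpaII tags per sample. It ranged from 5849116 to 16061807 tags, and the median site with at least 10 MspI tags had between 1 and 3 HpaII tags in a sample. The 28 pairs of samples were compared to look for a library deposited more than once. Their correlations across sites lay between 0.824 and 0.897, and the chi-square per site lay between 1.67 and 2.94, so all 8 samples were kept. The chi-square was 2.45 to 2.94 within the lingonberry group, 1.67 to 2.22 within HFD and 1.89 to 2.81 between groups. By the chi-square, spread between libraries was larger in the lingonberry group, which also held the deepest libraries. By the correlations it was not, as these were 0.854 to 0.897 within the lingonberry group and 0.839 to 0.860 within HFD. The chi-square compares tags with counting error alone and can rise with depth, so it does not settle which group varied more. Whether depth sets the difference in chi-square was not tested. The labels give no batch and no pairing of samples between groups.

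The genome-wide level was the mean m-score per sample over the 920205 sites that were listed in all 8 files and had at least 10 MspI tags. Sites were also divided by the number of other listed sites within 500 bp into isolated sites (0), sites with 1 to 4 neighbours and clustered sites (5 or more), and by chromosome type (autosomes, X and Y). Group means were compared with two-sided exact permutation tests over the 70 assignments of 4 samples against 4, which cannot give a p below 0.0286, and the 6 classes were adjusted by the Benjamini-Hochberg method. Single sites (1310003 listed in all 8 files) and fixed 1 kb windows (831003) were tested with limma, using empirical Bayes moderation with a mean trend, with an adjusted p threshold of 0.05. Counts at an unadjusted p below 0.05 are to be read against the share of 0.05 of all tests that chance gives. The sites and windows named are the 10 with the smallest adjusted p in each direction, summarised where they resemble each other. Features chosen after their values were seen are identified as such.

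Several analyses were added after the data were seen. These were HpaII tags per 1000000 by class and m-score, 1 Mb bins with at least 50 sites, clusters of at least 5 sites with gaps of at most 500 bp, and tests limited to sites with a mean of 10 tags or more, on the m-score and on log2 tags per 1000000 with a pseudocount of 0.5. Factors for local site density were also estimated per sample. For these, the 104166 sites with a mean m-score of 75 or above, at least 10 MspI tags and no shared tags were grouped by the number of neighbours within 500 bp and within 5000 bp, and each sample's tags were divided by its relative tag rate in the group, with each site capped at 200 tags per 1000000. This correction takes as unchanged the methylation of those sites. Alternatives fixed before the data were examined covered the scaling of tags (median of ratios for sites and windows), the MspI minimum, filters on low tags, thinning to the smallest library (for the genome-wide level), window and neighbour distances, autosomes alone and leaving out each sample.

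The limma steps were tested on simulated tags with a negative binomial dispersion of 0.1 and 200 changed features. The dispersion was set, not estimated from the data. Tags were drawn independently at each site, with no difference between libraries apart from depth. Where real neighbouring sites vary together within a library, recovery in clusters and bins would be lower than simulated. Changed sites were drawn only from those with at least 10 MspI tags and a mean of at least 10 HpaII tags. With all 1310003 sites tested, 0 of 100 sites with a 2-fold change and 3 of 100 with a 4-fold change were recovered, while 216 unchanged sites were called. Among 920205 sites with at least 10 MspI tags, 0 of 100 at either size were recovered and 73 unchanged sites were called. For sites with a mean of 10 tags or more, log2 tags recovered 2 of 93 at 2-fold and 57 of 79 at 4-fold, with 1 unchanged site called, while the m-score recovered 0 of 93 and 0 of 79 with 0 unchanged sites called. Changed windows of 1 kb were drawn from those with at least 3 sites and a mean of at least 10 tags. They gave 0 of 100 and 18 of 100 with 147 unchanged windows called. Clusters gave 58 of 100 and 86 of 100 with 4 unchanged clusters called. Bins of 1 Mb recovered 29 of 100 at 1.1-fold and 69 of 100 at 1.2-fold, with 7 unchanged bins called. The unchanged sites and windows called in the simulation were of the same order as the 176 sites and 128 windows called in the deposited data.

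Promoters, gene bodies and gene lists, including lists of liver cell type markers, were not tested. The annotation at hand was of the assembly GRCm38.p6, and no coordinates were converted from mm9, so positions are given in mm9 without gene names. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3, limma 3.58.1 and matplotlib 3.10.9.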

Results

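Hepatic DNA methylation was profiled at HpaII sites in C57BL/6J mice fed a high-fat diet (HFD) with lingonberries (n = 4) or the HFD alone (n = 4), to ask whether the berry supplement altered methylation genome-wide. Methylation is given as the m-score, which runs from 0 at the methylated end to 100 at the unmethylated end. As the MspI reference was scaled to each sample's HpaII total, the score is relative to the other sites of the sample. A lower m-score means more methylation relative to those sites, and a change of tags in equal proportion at all sites would cancel. The mean m-score is thus no absolute level of methylation. The 4 lingonberry samples held 16061807, 9954995, 6094809 and 10191631 HpaII tags. The 4 HFD samples held 7009395, 6502007, 5849116 and 7403696, so the deepest libraries were in the lingonberry group. In all, 1310003 sites were listed in every sample and 920205 of them had at least 10 tags in the shared MspI reference. The study's design gives 4 mice per group, and p-values measure the spread between these samples.

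The livers of lingonberry-fed mice had a lower mean m-score than those of HFD mice. It was 28.5 ± 0.40 with lingonberries and 29.8 ± 0.61 without (SD, n = 4 each), a difference of -1.36, and all 4 lingonberry samples lay below all 4 HFD samples (exact permutation test, two-sided p = 0.0286, the smallest possible). The share of sites with an m-score below 25, the methylated part of the scale, was 58.6% ± 0.87 with lingonberries and 55.4% ± 1.60 without (SD, n = 4, exact p = 0.0286). Sites of intermediate m-score, from 25 to 75, made up 28.1% ± 0.59 and 31.4% ± 1.62 (exact p = 0.0286). The share of unmethylated sites, at 75 or above, was 13.4% ± 0.30 and 13.2% ± 0.14 and did not differ by the test (exact p = 0.343). This share pools opposite directions by local site density, none past the threshold. It was 2.49% ± 0.70 with lingonberries and 3.69% ± 0.77 without at isolated sites (exact p = 0.0857). At clustered sites it was 57.4% ± 2.59 and 51.5% ± 3.29 (exact p = 0.0571). Sites with 1 to 4 neighbours had 9.0% ± 0.54 and 9.4% ± 0.36 (exact p = 0.171). The mean m-score was lower with lingonberries on all 21 chromosomes, and 18 passed after Benjamini-Hochberg adjustment over the 21. The chromosomes come from the same 8 samples and share the genome-wide shift, so these counts are no independent evidence. The median over sites differed by -3.43 (exact p = 0.0286). The call on the mean was lost with a MspI minimum of 1 tag (-1.27) and without lingonberry sample 2 (-1.18, exact p = 0.0571 for each). With a MspI minimum of 50 tags the difference was 0.019 (exact p = 0.857), and with tags divided by factors for local site density it was -0.59 (exact p = 0.343).

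The difference depended on how densely HpaII sites lay. Isolated sites (339261), with no other site within 500 bp, had a mean m-score of 17.5 ± 0.42 with lingonberries and 20.3 ± 1.26 without, a difference of -2.80 (SD, n = 4, exact p = 0.0286, adjusted p = 0.0429 over 6 classes). Sites with 1 to 4 neighbours (452303) had 24.9 ± 0.62 and 26.1 ± 0.66, a difference of -1.22 that did not pass the correction (exact test, adjusted p = 0.0686). Clustered sites (128641), with 5 or more neighbours, are largely unmethylated, as CpG-rich sequence commonly is. Their mean m-score was 70.03 ± 0.92 with lingonberries and 68.08 ± 1.19 without, a difference of 1.94 in the opposite direction that did not pass (exact test, adjusted p = 0.0857). The difference between the isolated and the clustered class was itself tested, and the isolated minus clustered m-score was -52.6 ± 1.28 with lingonberries and -47.8 ± 2.45 without, a difference of -4.75 (SD, n = 4, exact p = 0.0286). Autosomes differed by -1.36, the X chromosome by -1.40 and the Y chromosome by -1.87 (253 sites), each with an adjusted p of 0.0429 in the exact test. Dividing tags by factors for local site density left -0.30 at isolated sites (exact test, adjusted p = 0.823), -1.01 at sites with 1 to 4 neighbours and 0.12 at clustered sites. The isolated minus clustered difference was not tested again with these factors. Without lingonberry sample 1, 2 or 4 the calls at isolated sites, on autosomes and on the X chromosome were lost (exact tests over 7 samples, adjusted p from 0.0571 to 0.0857), while the differences were from -2.79 to -2.68, from -1.50 to -1.17 and from -1.48 to -1.38. On the Y chromosome the call was lost without any 1 of the 4 lingonberry samples, with differences from -2.04 to -1.67 (adjusted p from 0.0686 to 0.0857). At isolated sites and on autosomes, X and Y, all lingonberry samples lay below all HFD samples, so this order stays whichever sample is left out. At isolated sites the highest lingonberry value was 18.1 and the lowest HFD value 19.2. With 3 samples against 4, the exact p cannot fall below 0.0286 before adjustment over the 6 classes.

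**Figure D1:**
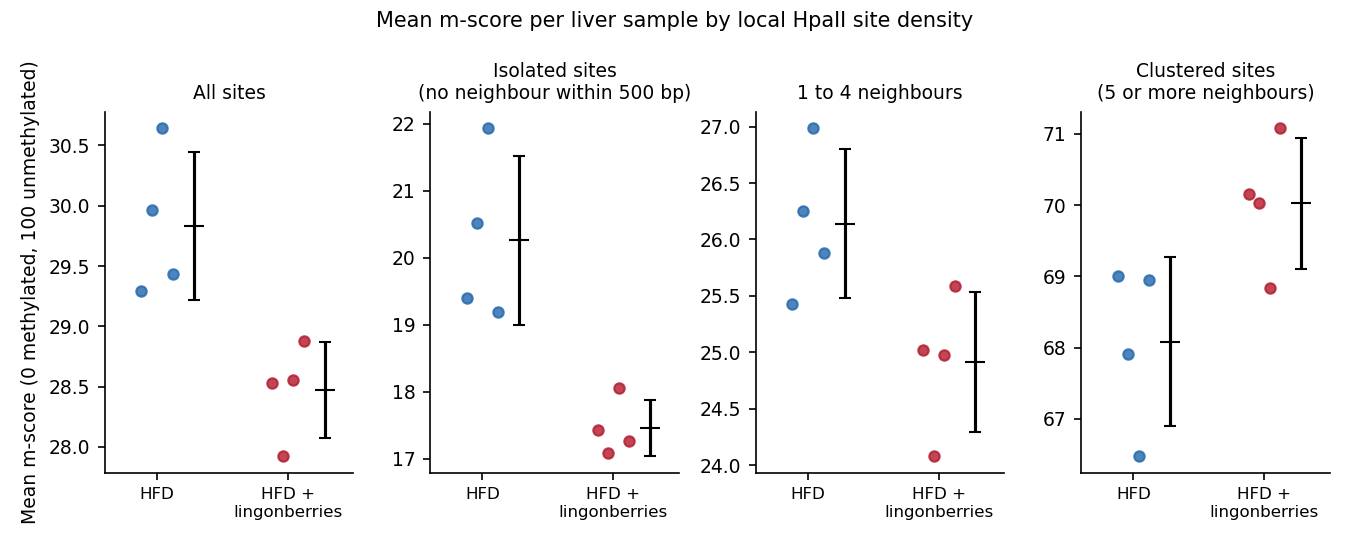
Mean m-score of each liver sample (points) on the vertical axes, with 0 the methylated and 100 the unmethylated end, for all sites and for 3 classes of local site density, with the group mean and SD (n = 4) beside the points. The vertical axes differ and do not start at 0. The lingonberry samples lie below the HFD samples at all sites and at isolated sites, and at clustered sites their mean is the higher one.

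HpaII tags, counted without the MspI reference, also differed by site density. This comparison was chosen after the data were seen. Shares and tags per 1000000 refer to a fixed total, as do m-scores through the scaled reference. A lower share in one class goes with a higher one elsewhere, so the directions are not separate findings, in tags or in m-scores. Isolated sites held 11.6% ± 0.93 of the tags at these sites with lingonberries and 14.6% ± 1.51 without (SD, n = 4, exact p = 0.0286). Clustered sites held 52.2% ± 1.61 and 47.8% ± 2.48 (exact p = 0.0286). At isolated sites that were partly methylated (mean m-score from 20 to 50), the log2 ratio of tags per 1000000, lingonberry over HFD, was -0.32 ± 0.09 (SE, exact p = 0.0286). At isolated sites that were unmethylated (75 or above), it was -0.36 ± 0.12 (SE, exact p = 0.0571). At clustered sites it was 0.14 ± 0.04 where partly methylated and 0.14 ± 0.05 where unmethylated (SE, exact p = 0.0286 for each). At sites with 1 to 4 neighbours it was -0.14 ± 0.06 where partly methylated (SE, exact p = 0.0571) and -0.00077 ± 0.032 where unmethylated (exact p = 1.0), and the unmethylated minus partly methylated ratio was 0.13 ± 0.07 (SE, exact p = 0.143).

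**Figure D2:**
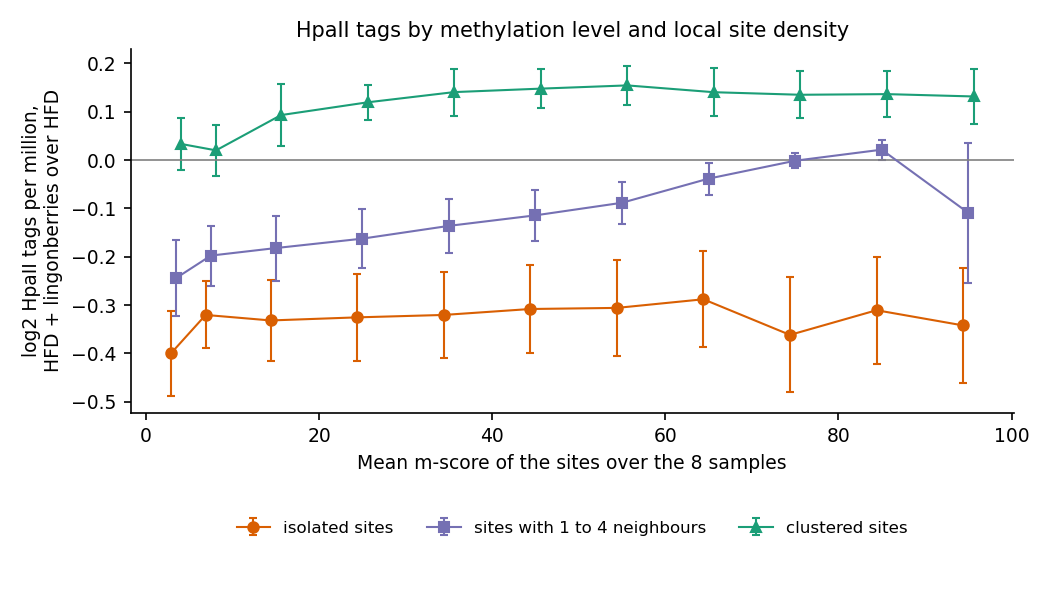
log2 ratio of HpaII tags per 1000000, lingonberry over HFD, on the vertical axis against the mean m-score of the sites over the 8 samples on the horizontal axis, for isolated sites, sites with 1 to 4 neighbours and clustered sites, from an m-score of 2 upwards. Points are means of 4 against 4 samples and bars are SE. The ratio at isolated sites stays below 0 and that at clustered sites above 0 at every m-score shown.

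Large regions followed the same division. Of 2539 bins of 1 Mb, 1452 had a lower mean m-score with lingonberries and 0 a higher one (limma, adjusted p below 0.05), and the median difference was -1.67. The bin at chromosome 10 from 103000001 to 104000000 (mm9), which has the smallest adjusted p and the lowest difference of those tied for it, had 15.8 ± 0.60 with lingonberries and 21.5 ± 2.05 without (SD, n = 4, limma adjusted p = 4.6e-05). It holds 106 sites, of which 74.5% are isolated, and like the bins as a whole it was chosen after the data were seen. Its limma p draws on the variance of all bins, which come from the same 8 samples, so it may be too small. With bins ranked by their percentage of isolated sites and divided into 4 sets, 110 of 635 passed as lower in the set with the fewest isolated sites and 528 of 635 in the set with the most. Before any threshold, 2510 of the 2539 bins had a lower mean with lingonberries. Across bins, which are not independent replicates, the difference had a Pearson r of -0.77 with the percentage of isolated sites. With density factors the count fell to 0 (170 at an unadjusted p below 0.05, limma, somewhat above the 0.05 share) and the median difference was -0.63.

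**Figure D3:**
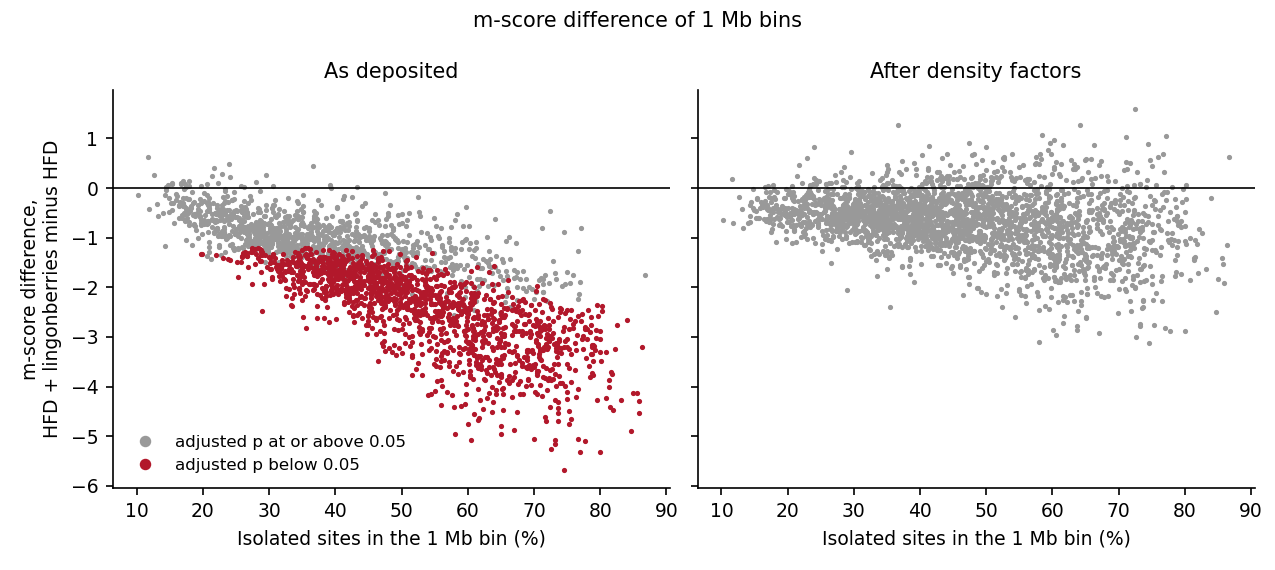
m-score difference of 1 Mb bins, lingonberry minus HFD, on the vertical axis against the percentage of isolated sites in the bin on the horizontal axis, as deposited (left) and after dividing tags by density factors (right). Each point is 1 of 2539 bins, and red points have a limma adjusted p below 0.05, which holds for 1452 bins on the left and 0 on the right.

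At single sites, 176 of 1310003 passed the test, 52 with a higher and 124 with a lower m-score with lingonberries (limma, adjusted p below 0.05). Of these, 173 had no HpaII tag in any sample of one group, and 89 had fewer than 10 MspI tags. All 10 sites named in each direction are of this kind. The site at chromosome 2, position 168273110 (mm9), had an m-score of 95.6 ± 1.92 with lingonberries and 0 in all HFD samples (SD, n = 4, limma adjusted p = 0.000225), from 23 tags against 0 and 1 MspI tag. The site at chromosome 1, position 165214554, had 92.9 ± 2.53 against 0, from 14 tags against 0. In the other direction, the sites at chromosome 1, position 67416023, chromosome 3, position 68575585, chromosome 4, position 151732296, and chromosome 8, position 118160928, each had 0 with lingonberries and 85.9 ± 1.37 without (SD, n = 4, limma adjusted p = 0.000225), from 4 HFD tags in all and 1 MspI tag. The 20 named sites had between 4 and 23 tags in the group with tags. No site passed among the 1093529 with at least 1 tag over all samples (43070 at an unadjusted p below 0.05, limma). That count is below the 0.05 share that chance gives. Leaving out 1 sample gave from 216 to 699 sites, and without lingonberry sample 3 the direction turned, with 524 higher and 175 lower. No site passed among the 133147 with at least 20 scaled tags in 4 samples (6852 at an unadjusted p below 0.05), and none did on the m-score or on log2 tags per 1000000 among 223293 sites with a mean of 10 tags or more (11349 and 12820, limma). Of these counts, 6852 and 11349 lie close to the 0.05 share of their tests, and 12820 somewhat above it. At sites with a mean of 10 tags or more the m-score test recovered 0 of 79 simulated 4-fold changes, so its count of 0 is not evidence of no change.

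Among 1 kb windows, 128 of 831003 passed, 40 higher and 88 lower with lingonberries (limma, adjusted p below 0.05), and 116 of them contained a single site. All 20 named windows are of 1 site, led by the window at chromosome 2 from 168273001 to 168274000, which contains the first site above. The 3 passing windows with 3 or more sites were singled out after their values were seen. The window at chromosome 18 from 83026001 to 83027000 had 44.6 ± 3.46 with lingonberries and 75.7 ± 2.15 without (SD, n = 4, limma adjusted p = 0.0187). The window at chromosome 8 from 92213001 to 92214000 had 0 and 3.75 ± 0.38 (limma adjusted p = 0.00452), and that at chromosome 8 from 98390001 to 98391000 had 3.16 ± 0.37 and 0 (limma adjusted p = 0.00699). Requiring at least 1 tag over all samples left 47 windows, and leaving out 1 sample gave from 186 to 451, and the direction turned without lingonberry sample 3 (336 higher, 115 lower) and without sample 2 (138 higher, 105 lower). When the 93862 windows with 3 or more sites were tested alone, 0 passed (5633 at an unadjusted p below 0.05, limma, somewhat above the 0.05 share).

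Clusters of HpaII sites showed no cluster past the threshold. Of 21020 clusters with at least 5 sites, 0 passed (limma, 1728 at an unadjusted p below 0.05; smallest adjusted p 0.602). On log2 tags per 1000000 0 passed as well (2709 at an unadjusted p below 0.05). Both unadjusted counts are above the 0.05 share, but the clusters come from the same 8 samples and are not independent evidence. On the autosomes 23.9% of 20674 clusters had a mean m-score of 75 or above, 53.3% lay between 25 and 75, and 22.9% lay below 25. On the X chromosome the shares of 345 clusters were 19.1%, 69.9% and 11.0%. The cluster with the smallest unadjusted p, at chromosome 10 from 116812888 to 116813840, had 77.9 ± 1.18 with lingonberries and 69.4 ± 2.10 without (SD, n = 4, limma adjusted p = 0.602) and did not pass.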

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

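The tests of explanations in this part were all chosen after the results they bear on were seen. Among 58 groups of 4 sample values tested for a sample far from the others, 0 had one, where chance gives about 2.9.

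The isolated minus clustered mean m-score differed between the diets by -4.75 (exact p = 0.0286), because isolated sites were lower and clustered sites higher with lingonberries. Unequal depth does not account for the lower m-score at isolated sites, since thinning all libraries to 5849116 tags left a difference of -3.06, and neither do a few sites with many tags, since scaling without the 1000 sites with most tags left -2.84. At isolated sites, a gain of methylation only at sites that still hold methylation would spare the unmethylated ones, yet their log2 tag ratio was as low as at partly methylated ones, with a difference of -0.046 ± 0.060 (SE). At sites with 1 to 4 neighbours the ratios were -0.14 where partly methylated and -0.00077 where unmethylated, a difference of 0.13 ± 0.07 (SE, exact p = 0.143), so such a gain stays open there. A library bias that follows local site density may account for the pattern: the log2 ratio at unmethylated isolated sites was -0.36 ± 0.12 (SE, exact p = 0.0571), and the difference at isolated sites went from -2.80 ± 0.67 to -0.30 ± 0.68 (SE) with density factors, which were themselves estimated from unmethylated sites and so remove any real change there. It covers little of the difference at sites with 1 to 4 neighbours, where the factors left -1.01 ± 0.54 of -1.22 ± 0.45 (SE, not past the threshold in either). An effect of the diet on methylation that depends on site density, and a difference in DNA or library quality between the groups, stay open and untested.

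For the lower m-score of 1 Mb bins, 1 of the 35 splits of the 8 samples into 4 and 4, the real one, gave as many as 1452 bins, and the highest other gave 16. The bins share the genome-wide shift, so this count repeats the separation of the samples seen in the genome-wide mean and is no independent evidence. The same library bias may account for the lower bins, but the density factors cannot tell it from a real change. They took the median bin difference from -1.67 (upper quartile -1.09) to -0.63 (upper quartile -0.33) and ended all calls. As they were estimated from unmethylated sites of the same samples, they also remove a real change that follows site density. The median SE of a bin went from 0.658 to 0.729, so the differences shrank and their errors grew somewhat, and 2301 of 2539 bins were still lower after the correction, which leaves a smaller shift open. No biological explanation was tested.

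Calls at single sites could come from chance: 7 of the 35 splits gave at least the real 176 sites, and the highest other gave 269. For 1 kb windows 5 of the 35 splits gave at least the real 128, and the highest other gave 169. Presence of a few tags against none describes 173 of the 176 sites. It also describes all 90 sites called with at least 10 MspI tags. For that count 1 of the 35 splits, the real one, was as large and the highest other gave 64, but simulated tags with the real library sizes gave 73 calls at unchanged sites, so false calls of about this number are not excluded. Of the 90 sites, 86 had 0 lingonberry tags and from 2 to 8 HFD tags. Most of the 86 had exactly 1 tag in each HFD sample. The HFD libraries were close in depth, from 5849116 to 7403696 tags, against 6094809 to 16061807 with lingonberries. Equal tags at close depths give nearly equal m-scores, so the spread was small in both groups. Whether this places the calls in the real split was not tested.

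A set of 634 sites had HpaII tags and no MspI tag in all 8 samples. Their m-score is fixed at 100 by the missing reference, and they are outside the comparisons of levels.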

How the results depend on the processing

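Alternatives with density factors, thinned libraries (except for the genome-wide level, where thinning was planned), log2 tags, sites without shared tags, sites of mean 10 tags or more, windows of 3 or more sites, scaling without the 1000 sites of most tags and, for levels, median-of-ratios scaling were added after the data were seen. No paired analysis was possible, as the labels pair no samples between the groups. Of 20 alternatives for the genome-wide level, 16 kept direction and significance, among them the median over sites, with a difference of -3.43, and median-of-ratios scaling, with -0.92. Many of these could hardly differ from the main setting, so the tally is no measure of stability. Leaving out 1 sample cannot change the order of the others. Autosomes alone, scores recomputed with per-million scaling and sites without shared tags each gave -1.36, as in the main setting. The genome-wide difference was -1.27 with a MspI minimum of 1 (exact p = 0.0571, the call lost) and -0.59 with density factors. With a MspI minimum of 50 it was 0.019 (exact p = 0.857), so no difference was seen at those sites. Which site classes they belong to was not examined. Leaving out 1 sample gave -1.54 to -1.09, losing the call without lingonberry sample 2 (exact p = 0.0571). With density factors isolated sites had -0.30, autosomes -0.59, the X chromosome -0.48 and the Y chromosome -0.24, none past the threshold, while sites with 1 to 4 neighbours kept -1.01 of -1.22 (not past it in either). Sites with 1 to 4 neighbours passed with neighbours within 1000 bp (-1.72), a MspI minimum of 20 (-1.10) and thinned libraries (-1.49). Leaving out 1 sample gave -3.16 to -2.24 at isolated sites, -1.46 to -0.94 at sites with 1 to 4 neighbours, 1.41 to 2.34 at clustered sites (past the threshold without lingonberry sample 3), -1.54 to -1.09 on autosomes, -1.58 to -1.22 on X and -2.16 to -1.29 on Y.

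Against 176 sites and 128 windows, requiring 1 tag gave 0 sites (43070 at an unadjusted p below 0.05, limma) and 47 windows, 20 scaled tags 0 and 0 (6852 and 3424), a MspI minimum of 10 90 and 38, thinned libraries 531 and 307, and log2 tags 2 and 12. Sites of mean 10 tags or more gave 0 on the m-score and 0 on log2 tags (11349 and 12820), windows of 3 or more sites 0 (5633), and 10 kb windows 28. Leaving out 1 sample gave 216 to 699 sites and 186 to 451 windows. Without lingonberry sample 3 the split turned to 524 higher and 175 lower sites and 336 and 115 windows. Without sample 2 it turned for windows (138 and 105). The cause was not tested. Over the alternatives for the 40 named sites and windows, 557 values passed and 76 did not. These features were chosen for the smallest adjusted p in the same data, and many windows hold the same single sites. Features that a filter removed gave no value. The tally is therefore no evidence of stability. Every named site lost its call when 1 tag over all samples was required and on log2 tags. A count model was not run, because the design set limma for files that hold scores, although the recovered tags could have been used in one. A separate MspI offset per sample was not run, as the reference is shared. Promoter and gene list alternatives were not run for want of an mm9 annotation. Depth at single sites was low, with a median of 1 to 3 tags.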

Other observations

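The tests in this part were chosen after the data were seen. Clusters of HpaII sites, many of them unmethylated, gave 0 calls in the real split, as in all 35 splits of the samples (highest other 0), so the count says nothing against chance. Sites with a mean of 10 tags or more gave 0 calls on log2 tags, and all 35 splits gave at least that many (highest other 7). Both counts are absences of calls at this depth: simulated 2-fold changes were recovered in 58% of clusters and in 2 of 93 such sites, so changes of that size at single sites would mostly be missed. The simulation drew neighbouring sites independently, so 58% may be too high for real clusters.

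The median difference of clusters, lingonberry minus HFD, was -0.29 in 2393 clusters with a mean m-score below 10, -0.86 in 2371 from 10 to 25, -0.16 in 2220 from 25 to 50, 1.58 in 9031 from 50 to 75 and 1.55 in 5005 at 75 or above. With density factors these medians were -0.46, -1.31, -1.03, -0.035 and -0.0054. No cluster passed the test by itself, and the medians were not tested.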
